A study of Homo sapiens with 42 samples.

How the data were processed

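QuantSeq REV 3′-end sequencing libraries of MDA-MB-231 breast cancer cells were deposited as 3 tables. The first held cytoplasmic and nuclear RNA of LM2 cells (highly metastatic to the lungs, per the labels) and Par cells (poorly metastatic). The second held the same fractions of poorly metastatic cells after HNRNPC knockdown (gHNRNPC) or with a control (gCTRL), and the third total RNA of LM2 cells given 3 µM of a compound named T4, or an equal volume of DMSO, for 6 h and harvested at 6, 24 or 72 h. The 42 libraries form 14 groups of 3. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

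The authors deposited expected counts per transcript end or genomic position; per the submitters' processing notes, Salmon 0.14.1 and the hg38 genome were used. The file names had pointed to normalised values, for which the design held limma. The deposited values were instead estimated (expected) counts, whole in 98.3 to 98.8% of entries, so they were rounded and tested with edgeR, which the design held for counts. Each table has 94924 entries, 71604 transcript ends and 23320 positions. Transcript ends were matched to GENCODE 29 (GRCh38), which also gives every gene coordinate below: 66115 matched, 56493 of them in the same version. A position entry was given to the gene of the transcript entries it is listed with, since 99.8% of positions share chromosome and strand with the transcript entry above them. Only 9.81% of positions lie within the GRCh38 span of the transcript they are listed with. The reason was not tested, and no other assembly or conversion was tried. Pairs of positions were ordered by coordinate and strand, and pairs of transcript ends by their GENCODE 3′ ends, if in the same version. A transcript end was placed downstream of the positions listed with it, and of those listed with an end at or upstream of it. In the listing, 98.4% of 5452 runs of positions go from downstream to upstream. Of 5837 pairs of genes, taken from both strands, 98.0% put the transcript end downstream of its positions. In all, 89065 entries of 42145 genes were used, 16102 genes having at least 2 entries. The entries left out held 0.934 to 4.23% of the reads of a library.

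Depth was 0.798 to 2.3 M (M, mega) counts per library. Group means ± SD, in M, were 1.70 ± 0.137 and 2.04 ± 0.248 for LM2 and Par cytoplasm, 1.12 ± 0.287 and 1.18 ± 0.0744 for LM2 and Par nuclei, 1.98 ± 0.241 and 2.05 ± 0.136 for gHNRNPC and gCTRL cytoplasm, 1.35 ± 0.130 and 1.54 ± 0.115 for their nuclei, 1.40 ± 0.178, 1.49 ± 0.134 and 1.46 ± 0.0626 for DMSO at 6, 24 and 72 h, and 1.19 ± 0.234, 1.32 ± 0.103 and 1.42 ± 0.0591 for T4. The biological coefficient of variation estimated by edgeR was 36.7% in the LM2 and Par table, 18.8% in the knockdown table and 24.8% in the T4 table. On simulated data, with 200 genes changed by a log2 of 1 or 2 (190 to 198 of them past the expression filter), the expression test found 7.22 and 7.53% of those changed by 1 in LM2 against Par cytoplasm and nuclei, 50.0 and 40.2% after the knockdown, and 30.6, 27.3 and 24.7% for T4 at 6, 24 and 72 h. At a log2 of 2 it found 59.8 to 90.9%. At a log2 of 1 the test of site use found 12% in LM2 against Par, in cytoplasm and in nuclei. It found 20 and 26% after the knockdown in cytoplasm and nuclei, and 18, 29 and 18% for T4 at 6, 24 and 72 h. At a log2 of 2 it found 48 to 88%. False calls were 0.952 to 8.62% of the calls. The changed genes were among 7733 to 8871 tested for expression but only 636 to 899 tested for site use. A larger share of changed genes makes the adjusted threshold easier to pass. The percents for site use are therefore not comparable with those for expression, and may overstate power where few genes change.

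Site use was measured for the 2 most used sites of each gene, each with a mean of at least 10 counts, as the log2 ratio of distal to proximal reads. The edgeR quasi-likelihood test of the interaction of site and group was applied to 828, 899 and 636 genes in the LM2, knockdown and T4 tables, and 242, 269 and 170 genes whose order was unknown were left out. Both sites were transcript ends in 185, 224 and 142 genes, and both were positions in 127, 111 and 102. Expression was the sum of a gene's entries, tested in 8541, 9351 and 8035 genes after the edgeR expression filter and TMM scaling. A call is an adjusted p (Benjamini-Hochberg) under 0.05 within one comparison. There were 13 comparisons, 7 of them main ones: LM2 against Par and gHNRNPC against gCTRL in each fraction, and T4 against DMSO at each harvest. The others were nucleus against cytoplasm in Par and gCTRL cells and the differences between effects, tested as interactions.

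A total of 22 gene lists were tested with camera in limma (correlation 0.01), again with an estimated correlation, and with fry: cleavage and polyadenylation factors, hnRNP and SR protein genes, genes known for poly(A) site switching, nuclear-retained RNAs, epithelial, mesenchymal, lung metastasis signature, NF-kB, interferon-stimulated, immediate early, cell cycle, p53, hypoxia, heat shock, stress response, cholesterol, ribosomal protein, mitochondrially encoded and histone genes, and markers of immune cells and of fibroblasts and endothelium. Members are named only if measured. A list is said to pass by camera, and fry results are not given below. Fry also passed lists that camera did not, such as hnRNP genes in LM2 against Par cytoplasm (fry adjusted p = 0.016). Named genes followed a rule. The 5 largest changes each way in site use and in expression were taken (3 in comparisons other than the main ones). These were among called genes with a mean of at least 50 counts, a symbol that is not a clone or locus name, and 3 libraries that did not overlap the other 3 (true of 10% of splits by chance, and as a condition of the rule no separate evidence). The condition on overlap was not applied to differences between effects. Without any of these conditions, up to 4 members per list by smallest p were added in the main comparisons, and HNRNPC and PDLIM5 always. The text gives a part of these genes, and the libraries that a call needs where it was not kept without each library in turn. The comparisons, tests, lists, named-gene rule and alternative settings listed next were fixed before the data were examined.

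These settings were other pseudocounts, site filters and site pairs, limma on log2 values, diffSplice over all sites, the compared groups alone, a replicate block, no gene filter, median-of-ratios scaling, quantile normalisation, DESeq2, and leaving out each library. Replicate numbers were treated as pairing the libraries where libraries of one number deviated from their group means together in every pair (correlation above 0.1). This held for expression of LM2 against Par in nuclei (0.77, 0.88 and 0.27 for numbers 1, 2 and 3) and at 72 h for T4 against DMSO, in expression (0.51, 0.83 and 0.23) and site use (0.24, 0.61 and 0.19), and not elsewhere. No pair of the 42 pairs of libraries was alike within counting noise (chi-square per degree of freedom 1.48 to 65.8). Folds against a group at 0 are lower bounds against a floor of 3 counts over the group. These bounds, and the intervals given for groups with 1 to 3 counts, cover counting error only. Whether counting used the strand is not stated in the sources used here, so genes that overlap on opposite strands may share reads. A gene's share of reads in entries with non-whole values is given where it is high, below as percent non-whole. It counts all reads of such an entry, so it is not the share of reads split between entries. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.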

Results

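Changes are log2 values ± standard error of the edgeR fit. Levels are means ± SD in CPM (counts scaled to library size) or percent of reads at the distal site. Each group had n = 3 libraries. HNRNPC (chromosome 14, 21209136–21269494), which encodes an RNA-binding protein of the hnRNP family, was the target of the knockdown. Its level was 99.9 ± 13.1 CPM against 512 ± 32.1 CPM in gHNRNPC and gCTRL cytoplasm (−2.36 ± 0.19, adjusted p = 2.3e-09) with no overlap of libraries. In their nuclei it was 98.4 ± 16.0 CPM against 534 ± 96.2 CPM (−2.44 ± 0.20, adjusted p = 2.0e-09), again with no overlap. In LM2 cells HNRNPC was at 482 ± 13.7 CPM in the cytoplasm against 600.5 ± 86.9 CPM in Par cells (−0.32 ± 0.20, adjusted p = 0.34). In nuclei it was at 1071 ± 344 CPM against 1172 ± 161 CPM (−0.13 ± 0.20, adjusted p = 0.90). Neither was past the threshold. Fitting the cytoplasm alone put HNRNPC past it (−0.33, adjusted p = 0.026). After T4 it was at 349 ± 122, 347 ± 24.6 and 429 ± 92.6 CPM at 6, 24 and 72 h, against 394 ± 8.34, 361 ± 46.8 and 413 ± 39.5 CPM with DMSO. None passed (adjusted p = 0.68, 0.91 and 0.96).

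**Figure D1:**
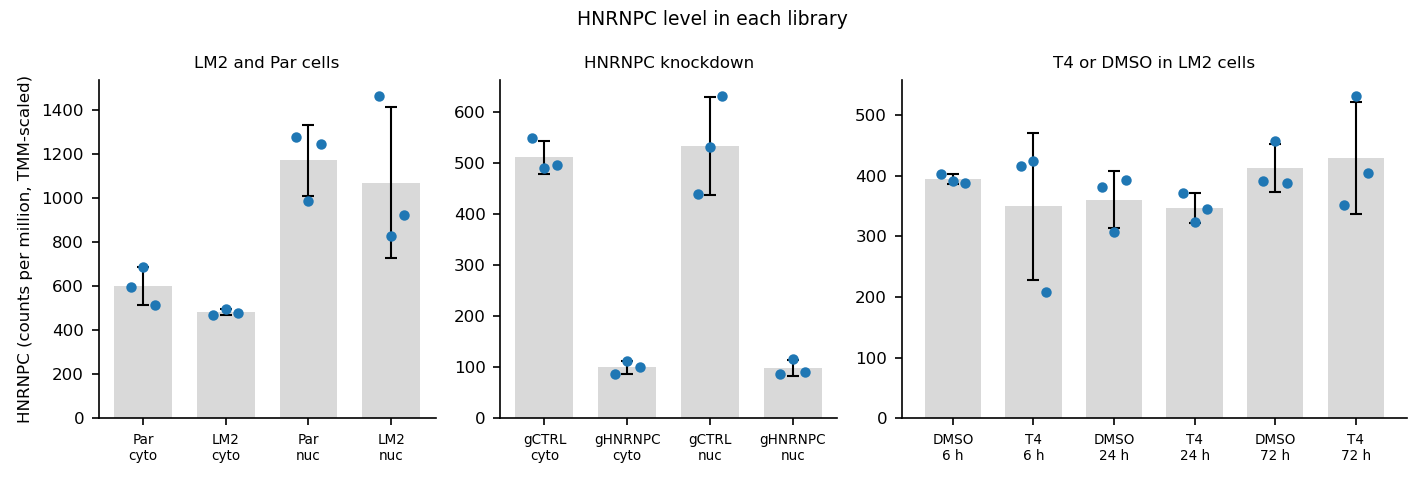
HNRNPC expression (CPM) in each of the 42 libraries by group. Points are libraries, and only the gHNRNPC groups were past the threshold against their controls.

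Among the largest differences between LM2 and Par cytoplasm, CSF3 and TFAP2C were higher in LM2 and CLDN4 and MXRA8 lower. CSF3, which encodes the cytokine G-CSF (chromosome 17, 40015361–40017813), was at 55.2 ± 6.73 CPM in LM2 and at 0 in Par cytoplasm (at least 115-fold higher, adjusted p = 3.5e-06). TFAP2C, the transcription factor AP-2γ (chromosome 20, 56629302–56639283), rose to 179.9 ± 12.2 CPM against 11.8 ± 2.60 CPM (+3.92 ± 0.29, adjusted p = 1.2e-05). PDE2A, a cGMP-stimulated phosphodiesterase, rose as well (+2.79 ± 0.32, adjusted p = 3.7e-04). So did SLCO4A1-AS1, antisense to SLCO4A1 (+2.51 ± 0.29, adjusted p = 3.8e-04), and NNMT, nicotinamide N-methyltransferase (+2.22 ± 0.33, adjusted p = 0.0018). CLDN4, a claudin of tight junctions (chromosome 7, 73799542–73832693), fell to 1.27 ± 1.28 CPM against 30.5 ± 4.0 CPM (−4.54 ± 0.50, adjusted p = 2.7e-04). MXRA8, an alphavirus receptor (−3.95 ± 0.25, adjusted p = 3.5e-06), and SPANXB1, a cancer-testis antigen with 86% of its reads in non-whole entries (−3.46 ± 0.31, adjusted p = 3.8e-05), fell. ARPC1B, a subunit of the Arp2/3 complex (−3.23 ± 0.28, adjusted p = 3.5e-05), and GAS6, a ligand of AXL (−3.08 ± 0.57, adjusted p = 0.010), fell as well. In all, 374 genes rose and 665 fell by edgeR. The split between them depends on the scaling: 521 and 453 with median-of-ratios, 540 and 449 with DESeq2 and 323 and 248 after quantile normalisation. The total of 1039 was 427, 464 and 340 without LM2 cytoplasm library 1, 2 or 3. It was 366 and 352 without Par cytoplasm library 1 or 2. Across the other settings it ranged from 292 with library totals to 2537 with the cytoplasm alone.

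Of 6 epithelial genes measured in cytoplasm, 0 rose, 4 fell and 2 were not past the threshold (0 rose and 4 fell when adjusted over the list alone). Their median was −1.06 (camera adjusted p = 1.0e-04, adjusted p = 0.030 with an estimated correlation). Besides CLDN4 they included JUP, plakoglobin (−2.29 ± 0.24, adjusted p = 1.9e-04), and KRT19, a keratin (−1.33 ± 0.16, adjusted p = 5.1e-04). Another 5 lists passed with the preset correlation only. Of 15 interferon-stimulated genes, 0 rose, 3 fell and 12 were not past the threshold (1 rose and 7 fell when adjusted over the list alone). Their median was −0.87 (adjusted p = 0.018, adjusted p = 0.0998 with an estimated correlation). BST2, which encodes tetherin, fell (−2.69 ± 0.22, adjusted p = 2.0e-05). IFI27 fell too, with 3 reads in LM2 and 70 in Par libraries (18.5-fold lower, 6.06 to 91.7). NF-kB inflammatory genes (2 higher and 1 lower of 9, 2 and 1 over the list alone) passed toward higher. They had a median of +0.32, or +0.24 with CSF3 at its bound (adjusted p = 0.042, adjusted p = 0.15 with an estimated correlation). CSF3 and IL11, a cytokine (+1.49 ± 0.21, adjusted p = 0.0016), were the higher ones. Lung metastasis signature genes gave 4 higher and 1 lower of 12, 5 and 1 over the list alone. Their median was +0.29, or +0.05 with genes at 0 at their bound (adjusted p = 0.042, adjusted p = 0.15 with an estimated correlation). COL6A1, a collagen VI chain, rose (+1.53 ± 0.23, adjusted p = 0.0019). These genes were chosen in earlier work on sublines of MDA-MB-231, so they are not independent evidence. Genes known for poly(A) site switching gave 0 higher and 6 lower of 27, 0 and 7 over the list alone. Their median was −0.24 (adjusted p = 0.042, adjusted p = 0.28 with an estimated correlation). TIMP3, a metalloproteinase inhibitor, fell (−1.78 ± 0.25, adjusted p = 0.0015). For mitochondrially encoded genes the counts were 2 higher and 0 lower of 12, 3 and 0 over the list alone (median +0.34, adjusted p = 0.042, adjusted p = 0.52 with an estimated correlation). MT-RNR1 rose (+1.25 ± 0.21, adjusted p = 0.0039).

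The other 13 of 19 lists tested had adjusted p = 0.057 to 0.96. The counts were 0 higher and 5 lower of 23, 0 and 8 over the list alone, for hnRNP genes. HNRNPF (−1.83 ± 0.28, adjusted p = 0.0019) and HNRNPH2 (−0.87 ± 0.14, adjusted p = 0.0031) were among those that fell. For stress response genes they were 3 higher and 1 lower of 20, 5 and 2 over the list alone, and PHGDH, a serine synthesis enzyme, rose (+3.18 ± 0.48, adjusted p = 0.0018). For hypoxia and glycolysis genes they were 1 higher and 5 lower of 14, 1 and 6 over the list alone. The hormone precursor ADM rose (+2.33 ± 0.36, adjusted p = 0.0022) and the hexokinase HK2 fell (−1.74 ± 0.33, adjusted p = 0.0064). For cleavage and polyadenylation factors they were 0 higher and 2 lower of 26, 0 and 1 over the list alone, SR protein genes 0 higher and 0 lower of 16, 0 and 0 over the list alone and mesenchymal genes 1 higher and 1 lower of 12, 2 and 1 over the list alone. For cell cycle genes they were 1 higher and 2 lower of 31, 0 and 1 over the list alone, heat shock genes 0 higher and 2 lower of 12, 1 and 3 over the list alone and immediate early genes 3 higher and 2 lower of 12, 3 and 2 over the list alone. For p53 targets they were 0 higher and 3 lower of 11, 1 and 3 over the list alone, with a median of +0.23 and a mean of −0.01. For cholesterol genes they were 1 higher and 2 lower of 17, 1 and 2 over the list alone, ribosomal protein genes 1 higher and 0 lower of 29, 1 and 0 over the list alone and nuclear-retained RNAs 0 higher and 0 lower of 8, 0 and 0 over the list alone. Replication-dependent histone genes, too few for the test, gave 0 higher and 0 lower of 2, 0 and 0 over the list alone. Of the markers of other cell types, the only immune one measured was CD68 (at most 65.5 CPM in any library of either fraction, log2 −0.06, not past the threshold). The only fibroblast or endothelial one was COL1A1, a fibrillar collagen. It had 42 reads in LM2 and 3 in Par cytoplasm (17.7-fold higher, 5.65 to 89.2, adjusted p = 0.0076). In nuclei it had 163 and 1 (176-fold, 31.1 to 6988, adjusted p = 3.2e-04).

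In nuclei CSF3, TFAP2C, PDE2A, CLDN4 and MXRA8 moved the same way. CSF3 was at 254 ± 42.7 CPM against 0.660 ± 0.594 CPM in LM2 and Par nuclei (816 and 2 reads, 440-fold, 121 to 3641, adjusted p = 1.4e-06). TFAP2C rose (+3.54 ± 0.29, adjusted p = 2.7e-05) and PDE2A was at 109 ± 1.80 CPM against 11.1 ± 5.62 CPM, log2 +3.25 ± 0.33, adjusted p = 1.4e-04. CLDN4 fell to 8.01 ± 2.24 CPM against 394 ± 42.8 CPM (−5.62 ± 0.45, adjusted p = 2.3e-05). MXRA8 fell (−3.82 ± 0.22, adjusted p = 2.0e-06), and so did BST2 (−3.00 ± 0.22, adjusted p = 1.1e-05) and SPANXB1 (−3.34 ± 0.31, adjusted p = 6.4e-05). NNMT rose (+2.58 ± 0.35, adjusted p = 0.0014) and VAMP8, a SNARE protein of vesicle fusion, fell (−2.78 ± 0.43, adjusted p = 0.0048). Both lost the call with nuclei alone (adjusted p = 0.12 and 0.14). In all, 118 genes rose and 114 fell. Of these, 94 and 84 genes moved the same way as in cytoplasm, against 5.17 and 8.88 for independent calls, with none opposite. Epithelial genes fell (0 higher and 4 lower of 6, 0 and 5 over the list alone, median −1.24, adjusted p = 7.9e-11, 0.0019 with an estimated correlation). Lung metastasis signature genes, chosen as said above, passed toward higher (5 higher and 0 lower of 12, 5 and 0 over the list alone). Their median was +0.76, or +0.36 with genes at 0 at their bound (adjusted p = 5.3e-08, 0.0026 with an estimated correlation). They were led by IL13RA2, an interleukin receptor (49.2 CPM in LM2 and 0 in Par nuclei, at least 56.9-fold). COL6A1 rose (+1.49 ± 0.21, adjusted p = 0.0015, not past it with nuclei alone, adjusted p = 0.056). NF-kB genes passed toward higher (2 higher and 0 lower of 9, 3 and 0 over the list alone, median +0.33, adjusted p = 0.0016, 0.040 with an estimated correlation). Interferon-stimulated genes passed toward lower (0 higher and 2 lower of 15, 0 and 3 over the list alone, median −0.16, adjusted p = 0.0055, 0.040 with an estimated correlation and 0.0503, not past it, when also blocked by replicate number). Cholesterol synthesis genes passed only with the block (adjusted p = 0.042, 0.13 with an estimated correlation). The remaining 15 of 19 lists had adjusted p = 0.059 to 0.96.

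Nuclear libraries numbered 2 stood apart in both lines. TUBD1 held 2.35% of the reads in LM2 and slightly less in Par, against 0.114 to 0.716% in the other libraries of that table. Their TMM factors were 0.721 and 0.731 against 0.962 to 1.22. The nuclear count of 232 was 128 without LM2 nuclei library 3 and 141 and 128 without Par nuclei library 1 or 3. It was 40 with nuclei alone and 65 with nuclei alone and without both libraries numbered 2. No gene differed between nuclei and cytoplasm in its LM2 change by edgeR (0 called, 798 at an unadjusted p under 0.05). DESeq2 called 4, limma 0 and 1 with pseudocounts 1 and 5, and edgeR 5 without Par cytoplasm library 3.

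Calls for poly(A) site use between LM2 and Par cells depended on the settings in cytoplasm. In cytoplasm, edgeR called 0 of 828 genes, with 170 at an unadjusted p under 0.05 (52 toward the distal site and 118 toward the proximal site). The smallest adjusted p was 0.051. Limma called 1, 11 and 2 with pseudocounts 1, 5 and 0.1, and diffSplice 86. By edgeR the count was 13 with a replicate block, 25 with site means of at least 50, 8 with no site filter, 8 with extreme sites and 12 with other annotation versions. The median change over all genes was −0.18. The median percent of reads at the distal site was 47.4 ± 0.664% in LM2 and 51.6 ± 2.34% in Par cytoplasm. The count depends on which libraries share the fit. It was 37 without Par cytoplasm library 3 and 189 (65 distal and 124 proximal) with the cytoplasm alone. It was 123 (34 and 89) without both nuclear libraries numbered 2, an alternative added after the data were seen. In nuclei edgeR called 0 (33 unadjusted, 0 by limma with each pseudocount and by diffSplice, and 1 with no site filter). The medians there were 57.9 ± 3.10% and 57.4 ± 2.43%. The difference between fractions gave 0 by edgeR (60 unadjusted, 0 by limma with each pseudocount and 1 by diffSplice). PDLIM5, a PDZ and LIM domain protein named before the data were examined (chromosome 4, 94451857–94668227), was at 21.4 ± 0.449% against 30.3 ± 5.13% in LM2 and Par cytoplasm (−0.66 ± 1.15, adjusted p = 0.82). It has 96% of its reads in entries with non-whole values and was not past the threshold in any of the 7 main comparisons.

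After HNRNPC knockdown, DHRS2 was among the genes that rose most, and SLCO4A1 and SLCO4A1-AS1 among those that fell most. DHRS2, a short-chain dehydrogenase (chromosome 14, 23630115–23645639), was at 256 ± 67.8 CPM against 3.86 ± 1.32 CPM in cytoplasm (+6.05 ± 0.32, adjusted p = 3.9e-13). DERL1, a membrane protein of ER-associated degradation (+3.23 ± 0.34, adjusted p = 1.4e-07), and the carboxypeptidase CPA4 (+3.08 ± 0.47, adjusted p = 2.2e-05) rose. The UDP-galactose transporter SLC35A2 (+3.04 ± 0.52, adjusted p = 1.2e-04) and CSKMT, which overlaps LBHD1 on the other strand (+4.16 ± 0.36, adjusted p = 1.2e-08), rose too. SLCO4A1, an organic anion transporter (chromosome 20, 62642445–62685785), fell to 98.7 ± 2.78 CPM against 924 ± 129.7 CPM (−3.23 ± 0.19, adjusted p = 2.5e-12) together with SLCO4A1-AS1 (−2.86 ± 0.25, adjusted p = 5.0e-09). The translation initiation factor EIF3C (−3.03 ± 0.23, adjusted p = 5.4e-10), the tubulin cofactor TBCD (−2.73 ± 0.23, adjusted p = 4.3e-09) and the small GTPase RAC3 (−2.69 ± 0.25, adjusted p = 1.8e-08) fell as well. In nuclei DHRS2 (+6.21 ± 0.35, adjusted p = 2.4e-12), CSKMT (+2.63 ± 0.28, adjusted p = 3.3e-07) and the cytokine GDF15 (773 ± 167 CPM against 121 ± 8.75 CPM, log2 +2.67 ± 0.20, adjusted p = 5.4e-10) were among the largest rises. DDIT3, also called CHOP (+2.61 ± 0.23, adjusted p = 7.5e-09), and RPL35A (+2.52 ± 0.32, adjusted p = 4.2e-06) rose too. SLCO4A1-AS1 (−3.17 ± 0.32, adjusted p = 7.3e-08) and EIF3C (−2.57 ± 0.24, adjusted p = 1.6e-08) fell most among named genes. SLCO4A1 (−2.41 ± 0.18, adjusted p = 7.0e-10) and CENPI, a kinetochore protein (−2.33 ± 0.33, adjusted p = 1.5e-05), also fell.

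In cytoplasm 1150 genes rose and 1163 fell after the knockdown (1533 and 862 with library totals alone). In nuclei 827 rose and 556 fell (591 and 770 with totals). Of these, 489 rose and 344 fell in both fractions, against 102 and 69.2 for independent calls, and none moved opposite ways. The nuclear count of 1383 was 878 without gCTRL nuclei library 2.

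Stress response genes rose after the knockdown. Of 22 integrated stress and unfolded protein response genes, 16 rose, 0 fell and 6 were not past the threshold (17 rose and 0 fell when adjusted over the list alone) in cytoplasm. Their median was +1.07 (camera adjusted p = 1.1e-14, 4.0e-04 with an estimated correlation). DDIT3 rose (chromosome 12, 57516588–57521737, 644 ± 47.0 CPM against 119.9 ± 13.8 CPM, log2 +2.43 ± 0.21, adjusted p = 4.3e-09), as did the transcription factor ATF5 (+1.79 ± 0.19, adjusted p = 1.2e-07) and SESN2 (+1.71 ± 0.19, adjusted p = 2.7e-07). In nuclei the counts were 16 higher and 0 lower of 22, 17 and 1 over the list alone (median +1.19, adjusted p = 1.0e-21, 9.0e-05 with an estimated correlation). Immediate early genes passed toward higher in cytoplasm (8 higher and 1 lower of 16, 8 and 2 over the list alone, adjusted p = 3.5e-04, 0.022 with an estimated correlation) and nuclei (8 higher and 1 lower of 16, 8 and 1 over the list alone, 2.3e-05 and 0.0078). FOSB (+3.75 ± 0.53, adjusted p = 6.3e-06) and EGR1 (+2.94 ± 0.33, adjusted p = 1.0e-06), both transcription factors, rose. Targets of p53 passed toward higher in cytoplasm, with the preset correlation alone (4 higher and 2 lower of 12, 6 and 2 over the list alone, adjusted p = 0.021, adjusted p = 0.093 with an estimated correlation) and nuclei (4 higher and 0 lower of 12, 4 and 0 over the list alone, 2.7e-04 and 0.015). GDF15 (+1.99 ± 0.23, adjusted p = 3.8e-07) and CDKN1A, the inhibitor p21 (+1.42 ± 0.17, adjusted p = 7.7e-07), rose in cytoplasm. Cell cycle genes passed toward lower in cytoplasm, with the preset correlation alone (0 higher and 9 lower of 29, 0 and 12 over the list alone, adjusted p = 0.019, adjusted p = 0.088 with an estimated correlation). The replication helicase subunits MCM5 (−1.46 ± 0.22, adjusted p = 2.8e-05) and MCM3 (−1.13 ± 0.19, adjusted p = 1.0e-04) were among those that fell. The list passed in nuclei too (0 higher and 7 lower of 29, 0 and 15 over the list alone, 1.2e-05 and 0.0078). There the ubiquitin-conjugating enzyme UBE2C fell (−0.96 ± 0.18, adjusted p = 5.1e-04).

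Other lists passed with the preset correlation alone. Hypoxia and glycolysis genes (1 higher and 6 lower of 14, 3 and 6 over the list alone, adjusted p = 0.044, adjusted p = 0.39 with an estimated correlation) passed toward lower in cytoplasm. Lactate dehydrogenase LDHA (−1.57 ± 0.24, adjusted p = 2.3e-05) and phosphoglycerate kinase PGK1 (−1.49 ± 0.29, adjusted p = 4.5e-04) were lower. In nuclei the list gave 1 higher and 5 lower of 14, 1 and 6 over the list alone (adjusted p = 7.2e-04, adjusted p = 0.10 with an estimated correlation). Heat shock genes in cytoplasm gave 3 higher and 0 lower of 12, 7 and 0 over the list alone, and the chaperone HSPA1A rose (+1.14 ± 0.28, adjusted p = 0.0040). The list had adjusted p = 0.022 (adjusted p = 0.23 with an estimated correlation). Mitochondrially encoded genes gave 6 higher and 0 lower of 12, 7 and 0 over the list alone in cytoplasm and 4 higher and 0 lower of 12, 4 and 0 over the list alone in nuclei (adjusted p = 0.0018 and 0.038, adjusted p = 0.55 and 0.61 with an estimated correlation). In nuclei, ribosomal protein genes gave 17 higher and 0 lower of 29, 25 and 0 over the list alone (median +0.64, adjusted p = 1.8e-10, adjusted p = 0.10 with an estimated correlation). RPL4 (+3.11 ± 0.52, adjusted p = 1.4e-04) and RPL32 (+2.31 ± 0.36, adjusted p = 5.5e-05) rose, and the cytoplasm counts were 2 higher and 1 lower of 29, 2 and 1 over the list alone. In nuclei hnRNP genes gave 1 higher and 4 lower of 23, 1 and 4 over the list alone (adjusted p = 0.0017, adjusted p = 0.14 with an estimated correlation), and PCBP2 fell (−1.73 ± 0.28, adjusted p = 1.1e-04). NF-kB genes gave 3 higher and 0 lower of 10, 3 and 0 over the list alone (adjusted p = 0.028, adjusted p = 0.10 with an estimated correlation), and IL11 rose (+2.41 ± 0.21, adjusted p = 9.3e-09). The remaining 13 of 20 lists in cytoplasm and 11 of 20 in nuclei had adjusted p = 0.063 to 0.94 and 0.052 to 0.98. CD68, an immune cell marker, rose in cytoplasm (+1.59 ± 0.39, adjusted p = 0.0038). CD14 was not past the threshold there, and the median of these markers was +2.59, or +0.80 with CD14 at its bound. In nuclei both rose, CD14 (+2.38 ± 0.57, adjusted p = 0.0052, adjusted p = 0.051 without gCTRL nuclei library 2) and CD68 (+1.29 ± 0.28, adjusted p = 0.0020, +0.71 and adjusted p = 0.067 without gHNRNPC nuclei library 2). The highest library of the knockdown table had 121 CPM of CD68. No fibroblast or endothelial marker passed the expression filter. In 2 genes the effect differed between fractions (982 at an unadjusted p under 0.05). Across the settings this count ranged from 1 to 36, the highest with no gene filter.

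**Figure D2:**
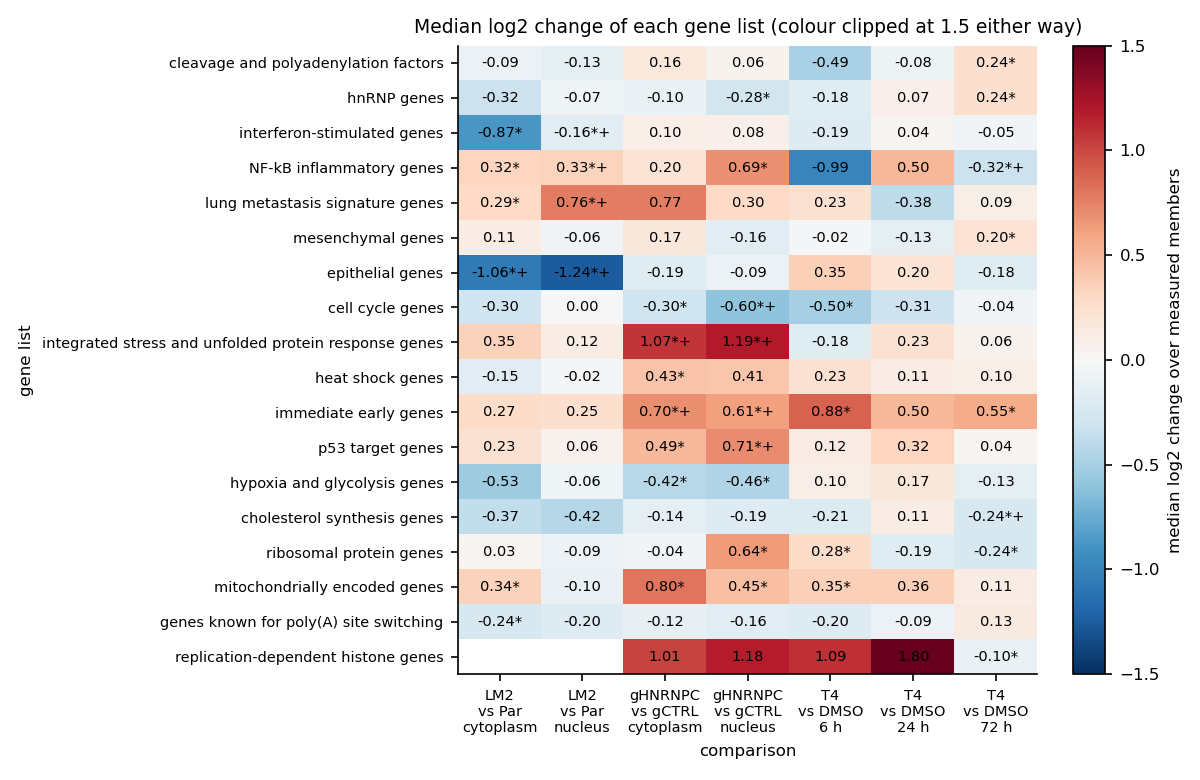
Median log2 change of each gene list in each comparison, with colour limited to 1.5 either way. A star marks a camera adjusted p under 0.05, and a plus that it also held with an estimated correlation.

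Poly(A) site use moved toward distal sites in most genes called after the knockdown. NUP214, of the nuclear pore (chromosome 9, 131125561–131234670), had 89.3 ± 2.70% against 28.7 ± 14.0% of its reads at the distal site in cytoplasm (+4.29 ± 0.55, adjusted p = 3.0e-05). BIRC5, or survivin (chromosome 17, 78214186–78225636), had 44.7 ± 3.59% against 6.94 ± 0.942% (+3.44 ± 0.35, adjusted p = 1.5e-06). SPECC1L had 64.0 ± 10.9% against 9.48 ± 4.19% (+4.16 ± 0.46, adjusted p = 4.5e-06). PGAP6, which MRPL28 overlaps on the same strand (+3.04 ± 0.55, adjusted p = 7.8e-04), and MRPL11, a mitochondrial ribosomal protein (+2.71 ± 0.51, adjusted p = 9.2e-04, not past it by limma with pseudocount 0.1, adjusted p = 0.098), moved the same way. Toward the proximal site moved ARNT, the partner of hypoxia-inducible factors (chromosome 1, 150809705–150876768, 49.8 ± 17.0% against 90.3 ± 4.24%, log2 −3.30 ± 0.57, adjusted p = 6.3e-04). NET1, an exchange factor for RhoA, did as well (50.2 ± 14.5% against 92.7 ± 4.24%, log2 −3.74 ± 0.58, adjusted p = 2.9e-04). So did EIF4A2, an initiation helicase (0 proximal and 1192 distal reads in gCTRL, 20 and 1667 in gHNRNPC, a ratio at least 4.77-fold lower, adjusted p = 0.0068, up to 0.13 with no site filter or by limma). C1orf21 also did (−2.56 ± 0.63, adjusted p = 0.0091, adjusted p = 0.052 without gHNRNPC cytoplasm library 3). TTLL12 moved likewise (−2.18 ± 0.60, adjusted p = 0.020, adjusted p up to 0.11 without gCTRL cytoplasm library 1 or gHNRNPC cytoplasm library 2 or 3). In all, 99 genes moved toward the distal and 29 toward the proximal site. The median over all 899 was +0.37, and the median percent distal was 54.4 ± 3.06% against 47.6 ± 1.97%. The count of 128 was 72 without gCTRL cytoplasm library 2 and 72 and 67 without gHNRNPC cytoplasm library 2 or 3. In cytoplasm, 21471, 21800 and 22853 sites were detected in gHNRNPC libraries and 20803, 20402 and 21101 in gCTRL libraries, without overlap. Over 552 genes the changes correlated at −0.409 with the deviation of library 3 of T4 at 6 h, a library of low complexity described below. Library quality was not tested as a cause of this distal shift.

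In nuclei 26 genes moved toward the distal and 14 toward the proximal site (median +0.16, 58.0 ± 2.58% against 55.3 ± 2.42%). BIRC5 (52.6 ± 11.3% against 10.2 ± 3.90%, log2 +3.33 ± 0.39, adjusted p = 2.2e-05), SPECC1L (+3.34 ± 0.48, adjusted p = 2.1e-04) and the nucleotide-sugar transporter SLC35C2 (+3.11 ± 0.55, adjusted p = 0.0017, adjusted p = 0.087 by limma with pseudocount 0.1) led toward distal sites. IVNS1ABP moved toward the proximal site (31.4 ± 14.9% against 73.6 ± 4.82%, log2 −2.69 ± 0.53, adjusted p = 0.0059). Calls for other leading genes needed single libraries: PGAP6 gHNRNPC nuclei library 2 (adjusted p = 0.054 without it), EIF4A2 gHNRNPC nuclei library 1 (0.066), and ARNT gCTRL nuclei library 2 and gHNRNPC nuclei libraries 1 and 2 (up to 0.13). Of the calls, 23 distal and 11 proximal ones were shared with cytoplasm, against 2.86 and 0.45 for independent calls (r = 0.57 over genes). The count of 40 was 18 without gCTRL nuclei library 2 and 20 and 20 without gHNRNPC nuclei library 1 or 2. No gene differed between fractions by edgeR (0 called, 62 unadjusted, 0 by limma with each pseudocount and by diffSplice).

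**Figure D3:**
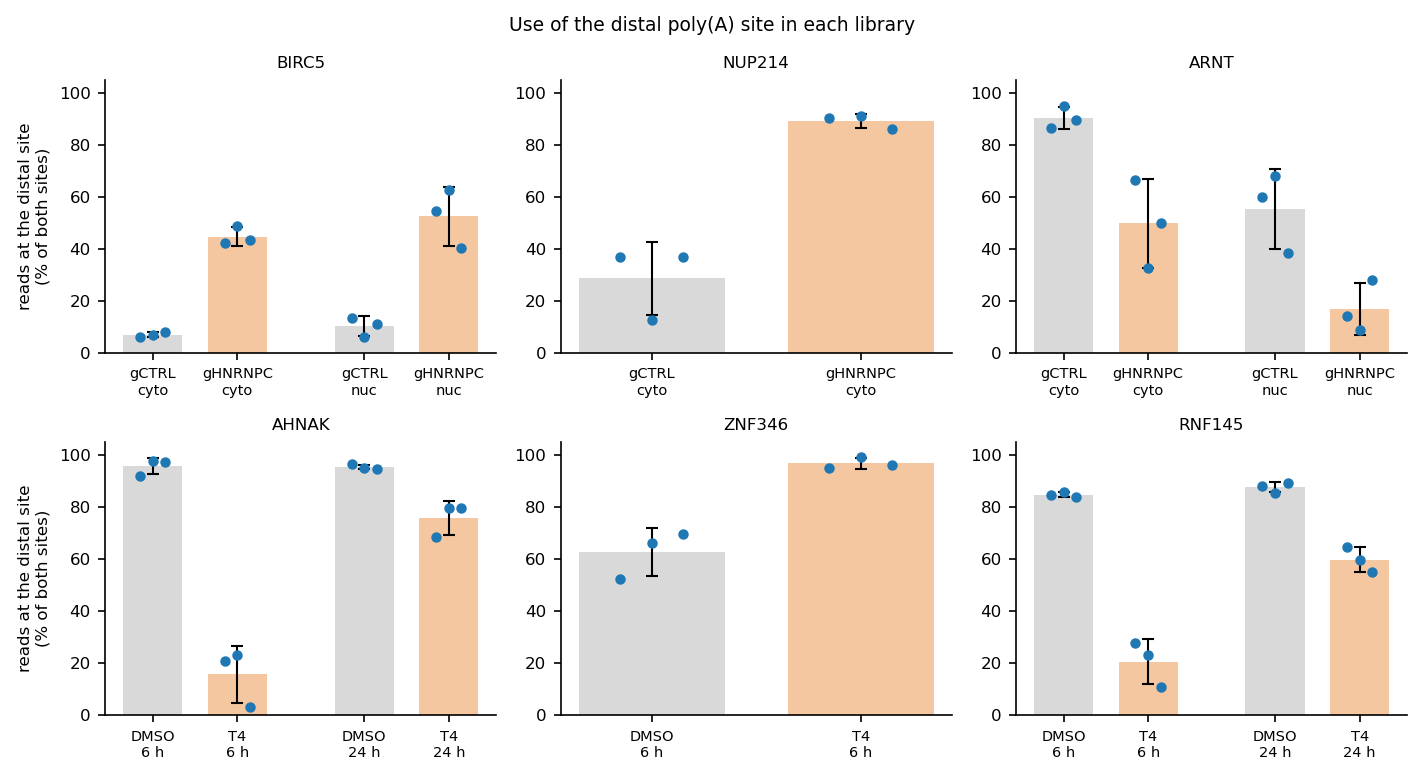
Percent of reads at the distal site for BIRC5, NUP214 and ARNT in gCTRL and gHNRNPC cytoplasm, and in nuclei where the gene was also named there. AHNAK, ZNF346 and RNF145 are shown in LM2 cells with DMSO or T4 at 6 h, and at 24 h where also named there. Points are libraries, bars means and whiskers SD.

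T4 lowered more genes than it raised at 6 h (1045 and 275). PPP1R10, or PNUTS, a protein phosphatase 1 subunit that acts in transcription termination (chromosome 6, 30600400–30618612), fell to 1.67 ± 1.46 CPM against 53.5 ± 5.21 CPM (−5.04 ± 0.48, adjusted p = 1.0e-06). BCAR3 (−3.52 ± 0.40, adjusted p = 1.4e-05) and FAM83G (−3.34 ± 0.26, adjusted p = 7.8e-07) fell with it, as did the ribosomal oxygenase RIOX1 (−3.27 ± 0.29, adjusted p = 1.0e-06) and HSD17B1-AS1, antisense to HSD17B1 (−3.19 ± 0.28, adjusted p = 1.0e-06). The AP-1 transcription factor JUNB (132 ± 61.7 CPM against 25.0 ± 3.05 CPM, log2 +2.43 ± 0.33, adjusted p = 8.5e-05) and IER3 (+2.43 ± 0.36, adjusted p = 2.0e-04) rose. The giant scaffold protein AHNAK (817 ± 299.8 CPM against 179 ± 1.24 CPM, log2 +2.19 ± 0.23, adjusted p = 6.2e-06), SNHG9 (+2.08 ± 0.29, adjusted p = 1.2e-04) and the BET protein BRD2 (+2.06 ± 0.29, adjusted p = 1.1e-04) rose too. Expression sums all entries of a gene, and after T4 most AHNAK reads of its 2 tested sites were at the proximal site, as given below. Its rise therefore does not show a rise of the mRNA that ends at the distal site. EREG, or epiregulin, a member of the lung metastasis signature list, rose to 32.1 ± 8.74 CPM against 1.44 ± 0.589 CPM (+4.41 ± 0.38, adjusted p = 1.0e-06). The split moves with scaling: 86 higher and 1689 lower with library totals, 263 and 530 after quantile normalisation and 619 and 945 with DESeq2. With the 6 h groups alone 421 genes were called. Library 3 of T4 at 6 h stood apart, with 11709 sites detected against 17241 to 21427 in the other T4-table libraries and 3.33% of reads on TUBD1 against 0.579 to 2.26%. Without it 1206 genes were called. Libraries 1 and 2 of T4 at 6 h also had fewer sites detected (17401 and 17241) than DMSO at 6 h (19038, 19031 and 19969). Library complexity and T4 therefore cannot be told apart at 6 h.

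Of 12 immediate early genes, 5 rose, 2 fell and 5 were not past the threshold (7 rose and 2 fell when adjusted over the list alone). Their median was +0.88 (camera adjusted p = 0.0023, adjusted p = 0.18 with an estimated correlation). FOS had 30 reads against 3 (15.5-fold, 4.83 to 79.5) beside JUNB and IER3. Cell cycle genes gave 0 higher and 10 lower of 29, 1 and 13 over the list alone (median −0.50, adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). The kinase AURKA (−1.46 ± 0.22, adjusted p = 1.9e-04) and CDC6, which loads replication helicases (−1.15 ± 0.24, adjusted p = 0.0031), fell. Ribosomal protein genes (2 higher and 0 lower of 28, 1 and 0 over the list alone) and mitochondrially encoded genes (1 higher and 0 lower of 12, 1 and 0 over the list alone) also passed (adjusted p = 0.0023 and 0.012, adjusted p = 0.18 and 0.36 with an estimated correlation). The remaining 16 of 20 had adjusted p = 0.070 to 0.78. Among them, 24 cleavage and polyadenylation factors gave 1 higher and 8 lower (2 and 8 over the list alone). SSU72, a phosphatase of RNA polymerase II, rose (+1.76 ± 0.32, adjusted p = 0.0011), and CPSF7 (−3.23 ± 0.50, adjusted p = 2.1e-04) and CSTF3 (−3.05 ± 0.45, adjusted p = 1.7e-04) fell. Stress response genes gave 0 higher and 6 lower of 19, 1 and 6 over the list alone, and DDIT3 (−2.40 ± 0.20, adjusted p = 7.8e-07) and PPP1R15A (−1.75 ± 0.28, adjusted p = 3.7e-04) fell. NF-kB genes gave 0 higher and 3 lower of 7, 0 and 4 over the list alone. IL11 (−1.41 ± 0.24, adjusted p = 5.1e-04) and RELB (−1.54 ± 0.32, adjusted p = 0.0033) fell, and NFKB2 was at 0 after T4 (at least 5.33-fold lower). The median was −0.99, or −0.60 with NFKB2 at its bound. SR protein genes gave 4 higher and 2 lower of 16, 5 and 2 over the list alone, and SRSF3 fell (−0.97 ± 0.20, adjusted p = 0.0023). Cholesterol synthesis genes gave 0 higher and 3 lower of 17, 0 and 3 over the list alone.

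At 6 h of T4, 10 genes moved toward the distal and 28 toward the proximal site. The median over all 636 was −0.35, and the median percent distal 45.7 ± 7.69% against 54.0 ± 0.995%. The 3 T4 libraries had 50.3, 50.04 and 36.8%, the last in library 3, against 52.9, 54.6 and 54.5% with DMSO, and the median change was −0.16 without T4 6 h library 3. AHNAK (chromosome 11, 62433542–62556235) had 15.7 ± 10.9% against 95.8 ± 3.12% of its reads at the distal site (−7.25 ± 0.70, adjusted p = 7.4e-07). RNF145, a ubiquitin ligase (chromosome 5, 159157409–159210053), had 20.6 ± 8.81% against 84.8 ± 0.940% (−4.41 ± 0.37, adjusted p = 1.0e-07). EIF4A2 (−4.85 ± 0.69, adjusted p = 1.5e-04) and ZNF557, with 67% of reads in non-whole entries (0 distal and 249 proximal reads, 36 and 216 with DMSO, at least 13.8-fold lower), moved the same way. Both lost the call with the 6 h groups alone (adjusted p = 0.050 and 0.096). Toward the distal site moved ZNF346 (96.8 ± 2.13% against 62.7 ± 9.21%, log2 +4.11 ± 0.57, adjusted p = 1.4e-04, 45% non-whole) and the mediator subunit MED22 (+3.64 ± 0.59, adjusted p = 5.2e-04, 57% non-whole). The topoisomerase TOP3A (+3.12 ± 0.54, adjusted p = 0.0012, 31% non-whole, adjusted p = 0.49 with the most distal and most proximal sites) and PHLDA1 (+2.43 ± 0.52, adjusted p = 0.0072, adjusted p = 0.19 with the 6 h groups alone) also did. GNE, with 98% of reads in non-whole entries, was called on 1 distal read (adjusted p = 0.048) and lost without any of the 6 libraries (adjusted p up to 0.14). The count of 38 was 23, 24 and 22 without DMSO 6 h library 1, 2 or 3, and 8 with the 6 h groups alone.

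By 24 h, 168 genes were higher and 240 lower (127 and 283 with median-of-ratios, 89 and 275 with library totals). By 72 h the counts were 8 and 11 (9 and 4 with library totals, 83 in all by DESeq2 and 120 without library 3 of T4 at 6 h). At 24 h IL11 fell to 47.0 ± 4.31 CPM against 216 ± 15.8 CPM (chromosome 19, 55364389–55370463, −2.20 ± 0.24, adjusted p = 6.4e-05). CSF3 fell (−1.90 ± 0.33, adjusted p = 0.0039), and so did the endosomal sorting protein SNX17 (−1.62 ± 0.25, adjusted p = 0.0022). GDF15 (chromosome 19, 18374731–18389176, 70.2 ± 14.0 CPM against 16.9 ± 1.76 CPM, log2 +2.05 ± 0.23, adjusted p = 7.9e-05) and DAB2, an endocytic adaptor (+1.85 ± 0.19, adjusted p = 4.2e-05), rose. RPL37 (+2.12 ± 0.34, adjusted p = 0.0026) and FAM43A (+1.94 ± 0.30, adjusted p = 0.0023) did too, as did EREG (+4.18 ± 0.32, adjusted p = 7.0e-07). At 72 h MMP1, a collagenase (chromosome 11, 102789920–102798160), was at 59.3 ± 10.9 CPM against 16.6 ± 0.244 CPM (+1.83 ± 0.25, adjusted p = 0.0014). CSF3 was at 23.2 ± 9.88 CPM against 113 ± 7.69 CPM (−2.29 ± 0.28, adjusted p = 7.1e-04, adjusted p = 0.064 with the 72 h groups alone). HIST2H2AA3 rose (+2.71 ± 0.33, adjusted p = 7.1e-04). GDF15 rose as well (+1.32 ± 0.21, adjusted p = 0.0081, adjusted p up to 0.077 without DMSO 72 h library 1 or 3 or T4 72 h library 1). INSIG1, a regulator of sterol synthesis, fell (−1.05 ± 0.19, adjusted p = 0.020, adjusted p up to 0.16 without DMSO 72 h library 2 or 3 or T4 72 h library 1 or 3, and 0.051 with a replicate block). Of genes called at 6 h, 34 higher and 43 lower were called the same way at 24 h, against 5.75 and 31.2 for independent calls, and 2 and 24 the opposite way.

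No list passed at 24 h by camera (20 of 20 at adjusted p = 0.070 to 0.96). The lowest was for cell cycle genes (1 higher and 4 lower of 29, 1 and 5 over the list alone), and the ribonucleotide reductase subunit RRM2 fell (−1.21 ± 0.23, adjusted p = 0.0064). At 72 h NF-kB genes (0 higher and 1 lower of 7, 0 and 2 over the list alone, adjusted p = 0.0010, 0.024 with an estimated correlation) and cholesterol synthesis genes (0 higher and 1 lower of 17, 0 and 4 over the list alone, 0.0010 and 0.024) passed toward lower. CSF3 belongs to the first and INSIG1 to the other. The other lists that passed lost it with an estimated correlation. Toward higher these were hnRNP genes (0 higher and 0 lower of 23, 3 and 0 over the list alone, 6.4e-04, adjusted p = 0.31 with it) and immediate early genes (0 higher and 0 lower of 12, 2 and 0 over the list alone, 0.0010, then adjusted p = 0.15). Histone genes (1 higher and 0 lower of 3, 1 and 0 over the list alone, 0.0026, then adjusted p = 0.089, median −0.10 and mean +0.64) followed. Cleavage and polyadenylation factors (0 higher and 0 lower of 24, 0 and 0 over the list alone, 0.011, then adjusted p = 0.30) and mesenchymal genes (0 higher and 0 lower of 10, 2 and 0 over the list alone, 0.029, then adjusted p = 0.25) did so as well. Toward lower it was ribosomal protein genes (0 higher and 0 lower of 28, 0 and 0 over the list alone, 0.0025, then adjusted p = 0.23). The remaining 12 of 20 had adjusted p = 0.16 to 0.98.

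Single libraries weigh on the later counts. The 408 at 24 h were 192, 163 and 220 without DMSO 24 h library 1, 2 or 3 and 143, 176 and 219 without T4 24 h library 1, 2 or 3. They were 1287 without library 3 of T4 at 6 h. The 19 at 72 h were 12, 8 and 6 without DMSO library 1, 2 or 3 and 7, 8 and 7 without T4 library 1, 2 or 3. They were 120 without library 3 of T4 at 6 h, 5 with the 72 h groups alone and 83 by DESeq2, and 7 with a block for the replicate numbers, which pair these libraries.

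For site use at 24 h, 9 genes moved toward the distal and 7 toward the proximal site (49.2 ± 2.62% against 53.8 ± 0.733% distal over genes). RNF145 remained toward the proximal site (59.9 ± 4.67% against 87.7 ± 2.02%, log2 −2.26 ± 0.35, adjusted p = 0.0018) and ANKRD1 moved toward the distal site (99.4 ± 0.360% against 96.2 ± 0.148%, log2 +2.81 ± 0.48, adjusted p = 0.0034). AHNAK (−2.73 ± 0.67, adjusted p = 0.042) lost its call without any of the 6 libraries (adjusted p up to 0.19) and with a replicate block (0.055). The count of 16 was 2, 5 and 6 without DMSO 24 h library 1, 2 or 3 and 2, 2 and 5 without T4 24 h library 1, 2 or 3. Across the other settings it ranged from 6 to 74, the highest with the 24 h groups alone. At 72 h no gene passed by edgeR (0 of 636, 20 unadjusted, 0 by limma with each pseudocount and by diffSplice). The medians were 55.1 ± 2.66% and 55.1 ± 2.29%.

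**Figure D4:**
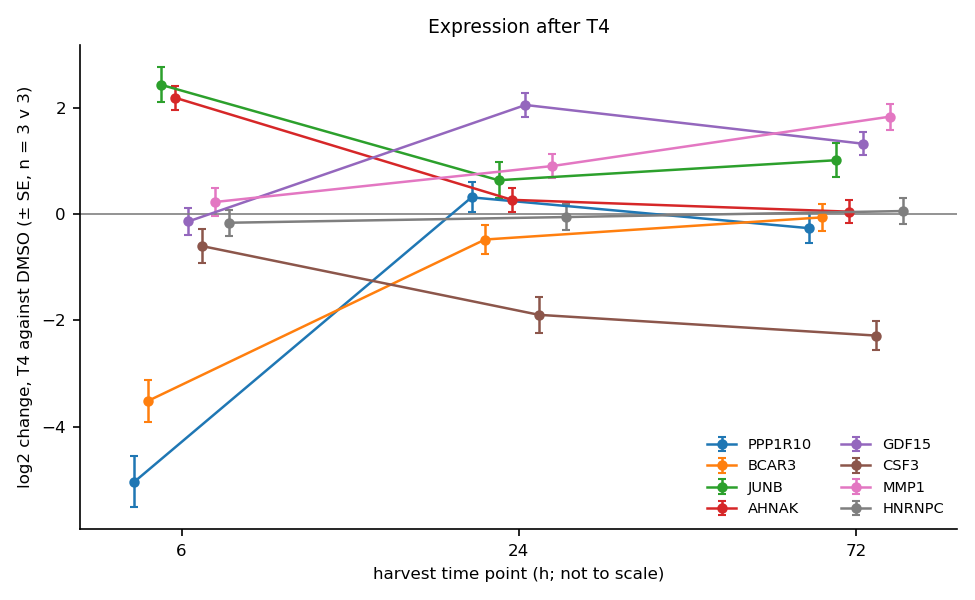
Log2 expression changes of T4 against DMSO for 8 genes at 6, 24 and 72 h after the start of treatment. Bars are standard errors of the edgeR fit.

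Nuclei and cytoplasm differed in both unperturbed groups. In gCTRL cells PSAP, the precursor of saposins, was at 8208 ± 779.6 CPM against 104 ± 6.10 CPM (+6.30 ± 0.29, adjusted p = 1.6e-15). The mitochondrial MT-CYB was at 3774 ± 541 CPM against 42.1 ± 12.7 CPM (+6.48 ± 0.27, adjusted p = 1.1e-15). ARPC1A, of the Arp2/3 complex, was lower in nuclei (−3.19 ± 0.20, adjusted p = 5.1e-13). In Par cells PPDPF (35.1 ± 7.70 CPM against 325 ± 33.7 CPM, log2 −3.21 ± 0.23, adjusted p = 4.3e-07) and ZNF358 (−3.24 ± 0.33, adjusted p = 9.4e-06) were lower in nuclei. ARHGEF26-AS1, antisense to ARHGEF26, was higher in nuclei there (368 ± 466 CPM against 9.46 ± 4.48 CPM, +5.27 ± 1.29, adjusted p = 0.010), with nearly all of its reads in non-whole entries and an SD above its mean. Par cells had 2105 genes higher and 1893 lower (1358 and 2338 after quantile normalisation) and gCTRL cells 3192 and 2622 (2641 and 3290). Of these, 1835 and 1644 were shared against 684 and 566 for independent calls (r = 0.89). Another 5 and 1 were opposite. HNRNPC was higher in Par nuclei (+0.97 ± 0.20, adjusted p = 0.0020, adjusted p = 0.20 after quantile normalisation), with a log2 of +0.06 in gCTRL cells. No list passed with an estimated correlation. With the preset one, mitochondrially encoded genes passed toward higher (12 higher and 0 lower of 12, 12 and 0 over the list alone in Par, adjusted p = 3.4e-11, adjusted p = 0.072 with an estimated correlation, and 12 higher and 0 lower of 12, 12 and 0 over the list alone in gCTRL, 2.7e-16, then adjusted p = 0.070). So did mesenchymal genes (10 higher and 0 lower of 12, 11 and 0 over the list alone, 2.2e-06, then 0.072, and 11 higher and 1 lower of 12, 11 and 1 over the list alone, 5.1e-07, then 0.065). Cholesterol synthesis genes did too (10 higher and 0 lower of 17, 10 and 0 over the list alone, 0.0027, then 0.072, and 13 higher and 2 lower of 17, 13 and 2 over the list alone, 0.0020, then 0.065), and so did lung metastasis signature genes, chosen as said above (7 higher and 2 lower of 12, 8 and 2 over the list alone, 0.013, then 0.072, and 7 higher and 1 lower of 11, 7 and 1 over the list alone, 0.0053, then 0.065). Ribosomal protein genes passed toward lower (1 higher and 22 lower of 29, 1 and 23 over the list alone, 5.5e-07, then adjusted p = 0.076, and 1 higher and 26 lower of 29, 1 and 26 over the list alone, 3.2e-11, then 0.093). The remaining 14 of 19 and 15 of 20 lists had adjusted p = 0.18 to 0.97 and 0.11 to 0.87.

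Distal sites were favoured in nuclei. In gCTRL cells 207 genes were more distal and 83 more proximal in nuclei (median +0.36). C19orf47, which PLD3 overlaps on the other strand, had the largest distal shift among named genes (82.6 ± 1.87% against 10.1 ± 1.47%, log2 +5.40 ± 0.36, adjusted p = 6.5e-10, 66% non-whole) and was more distal in Par nuclei too (+5.29 ± 0.92, adjusted p = 0.0060). AHNAK was at 98.1 ± 0.638% against 56.0 ± 9.80%, log2 +5.38 ± 0.48, adjusted p = 2.1e-08. HNRNPA1, an RNA-binding protein, was at 32.4 ± 10.2% against 1.67 ± 0.667%, log2 +4.83 ± 0.41, adjusted p = 2.1e-08. DAZAP2 was more proximal (63.0 ± 2.63% against 97.8 ± 0.837%, log2 −4.69 ± 0.39, adjusted p = 2.1e-08), as was EIF4A2 (at least 9.5-fold lower). PDLIM5 was more proximal as well (4.56 ± 1.26% against 15.9 ± 4.21%, log2 −1.98 ± 0.41, adjusted p = 0.0013, 96% non-whole). In Par cells 78 were more distal and 29 more proximal (median +0.25). DAZAP2 was again more proximal (73.1 ± 6.65% against 97.7 ± 0.466%, log2 −3.96 ± 0.35, adjusted p = 2.8e-05). More distal was SH2B3, a signalling adaptor (at least 6.56-fold higher, adjusted p = 0.081 by limma with pseudocount 5). The Par count of 107 was 33 and 26 without Par cytoplasm library 1 or 3 and 68 and 35 without Par nuclei library 1 or 3. The gCTRL count of 290 was 179 without gCTRL nuclei library 3. Of genes tested in both, 59 and 18 were called the same way, against 18.8 and 2.31 for independent calls (r = 0.81).

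Changes in site use after the knockdown and in LM2 cells ran opposite ways across genes in cytoplasm (r = −0.386 over 726 genes, Spearman −0.372, leave-one-out standard error 0.222, same sign in 34.8%). In nuclei they were near 0 (r = 0.058, standard error 0.109). T4 at 6 h went with LM2 against Par in cytoplasm (r = 0.376 over 581 genes, standard error 0.246, 0.113 without library 3 of T4 at 6 h). It gave −0.168 against the knockdown in cytoplasm (571 genes, standard error 0.183, −0.016 without that library). None of these correlations exceeded 2 standard errors, and the compared tables share no libraries.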

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

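Of the tests below, those of reads shared between sites, of starting usage and depth, of library quality and of power at 72 h were fixed before their results were seen, and all others were chosen after. The first 3 results below are listed because the effect differed between fractions or times by the interaction test of edgeR, the others to weigh explanations of patterns and to give the other splits of the libraries.

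After the knockdown, 2 genes differed between fractions in expression: EXOC3-AS1, antisense to EXOC3 and with 100% of reads in non-whole entries (+1.66, adjusted p = 0.011, up to 0.075 without gCTRL nuclei library 2 or gHNRNPC cytoplasm library 3 and 0.057 with a replicate block), and FKBP9, with 35% non-whole (−1.68, adjusted p = 0.0066). The count was 14, 1, 1 and 9 without gCTRL nuclei library 1 or 2, gHNRNPC cytoplasm library 3 or gHNRNPC nuclei library 2, and the call of FKBP9 was kept without each library. Of 100 splits, 13 gave as many calls (highest 897). The splits relabel libraries within each fraction, so some can carry the knockdown effect of a single fraction. They cannot decide whether the effects differ, and chance cannot be excluded.

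The T4 effect on expression differed between 24 h and 6 h in 759 genes (1252 without library 3 of T4 at 6 h), with PPP1R10 (+5.35), FAM83G (+4.0) and SMAD3 (+3.16) higher at 24 h relative to 6 h and AHNAK (−1.92), ARGLU1 (−2.10) and FOXC1 (−2.21) lower. Between 72 h and 6 h it differed in 782 (484 without DMSO 72 h library 1), with PPP1R10 (+4.77), FAM83G (+3.76) and BCAR3 (+3.45) against AHNAK (−2.14), PTGES (−2.41) and IER3 (−2.57). For 24 h, 1 of 100 splits gave as many calls (highest other 543), and for 72 h 4 of 100 did (highest other 1716). The splits exchange T4 and DMSO labels within each harvest, so they stand for no T4 effect at either time. Some of them can also carry the T4 effect of a single harvest. They therefore cannot decide whether chance explains a difference between times. The splits also took no account of the replicate numbers, which pair the 72 h libraries.

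In site use the T4 effect differed between 24 h and 6 h in 7 genes: AHNAK (+4.53), ANKRD1 (+4.31), MRPS25 (+3.04) and ZNF346 (−3.20) are the named ones. AHNAK lost the call without DMSO 6 h library 2 or 3, DMSO 24 h library 1, 2 or 3 or T4 24 h library 2 or 3 (adjusted p up to 0.10). ZNF346 lost it without each of 9 of 12 libraries (up to 0.13) and with a replicate block (0.079), and MRPS25 without a filter on site means (0.48). The count was 4, 2 and 2 without DMSO 6 h library 1, 2 or 3, 13 without T4 6 h library 3, 3, 3 and 2 without DMSO 24 h library 1, 2 or 3, and 4, 2 and 3 without T4 24 h library 1, 2 or 3. Between 72 h and 6 h it differed in 11 genes (17 and 18 without T4 6 h library 2 or 3), with ZNF557 (+7.0, a fitted value that is no bound, since T4 at 6 h has no distal reads), AHNAK (+5.45) and EIF4A2 (+4.86) against TOP3A (−3.96), MED22 (−4.25) and ZNF346 (−4.79). TOP3A was not past it with the most distal and most proximal sites (adjusted p = 0.73), nor EIF4A2 by limma with pseudocount 0.1, and ZNF557 lost it without each of 6 of 12 libraries (up to 0.092) and with a replicate block (0.051). Of 100 splits, 8 and 7 gave as many calls (highest 19 and 55). Such splits cannot decide whether effects differ, for the reason given above, so chance cannot be excluded.

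The opposite changes in site use after the knockdown and in LM2 cytoplasm could come from library quality. Given the deviations of the low-complexity T4 library and of the nuclear libraries numbered 2, the partial r over 552 genes moved to −0.140 from −0.377 (change 0.237 ± 0.093, range −0.242 to −0.028 without each library), the shift that this explanation predicts. Reads shared between sites, as far as non-whole values mark them, did not account for it. Over the 599 genes without non-whole values r was −0.389 (standard error 0.209), a change of −0.0027 ± 0.017, where this explanation needed a move to −0.19. Sharing that leaves whole values would escape this test and is not excluded. Starting usage (with DMSO) and depth were taken from the T4 experiment, not from the compared libraries, and did not bring r to −0.19. The partial r was −0.368 (standard error 0.239), a change of 0.0092 ± 0.0040. They accounted for 2.49 and 3.68% of the variance of the knockdown and LM2 changes. Usage and depth in the compared libraries were not tested, so they are not excluded. A lower HNRNPC level in LM2 cells predicts a positive r, so it gives no cause for opposite changes, although −0.386 lies within 2 standard errors of 0. The deviation of the low-complexity T4 library correlated at −0.409 with the knockdown changes and at 0.655 with the LM2 changes. Library quality stays open, and other differences between the lines were not tested.

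The shrinking of T4 differences from 6 h to 72 h is not explained by lower power: the SD of log2 changes beyond their error was 0.876, 0.549 and 0.267 at 6, 24 and 72 h, a ratio of 0.305 (0.247 to 0.437 without each library), where the bound for power was 0.8. Library 3 of T4 at 6 h does not account for the fall to 72 h either, since 1206 genes were called at 6 h and 120 at 72 h without it (1320 and 19 with it), and the SD ratio was 0.409. The fall in calls to 24 h depended on that library, since 1287 genes were called there without it and 408 with it. The T4 group at 6 h is then smaller than that at 24 h, so the counts at these times differ in power. The SD still fell from 0.840 to 0.553 between 6 and 24 h. A transient response to a 6 h exposure may remain as a hypothesis, which was not tested further. The lower numbers of sites detected in every T4 library at 6 h were not tested as an explanation.

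mRNAs translated at the endoplasmic reticulum were higher in the nuclear fractions: 28 of 31 such list genes in Par cells and 30 of 32 in gCTRL cells, and 0 lower in either. Their medians (+2.47 and +2.73) exceeded those of cytosolic genes of the same lists (−0.16 and −0.09) by 2.62 and 2.82. The pattern was first seen in these lists, so this comparison restates it and cannot show its cause. Endoplasmic reticulum kept with the nuclei and retention of transcripts in the nucleus both stay open. The median of nuclear-retained RNAs lay −1.14 (gCTRL) and −1.58 (Par) from that of the reticulum genes, yet its 8 members went both ways, with MALAT1 at +2.34 in Par and +3.26 in gCTRL cells.

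For comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. For expression, 2 of 10 splits gave as many calls as LM2 against Par in nuclei (232, highest other 1247), and 1 of 10 in every other comparison: LM2 cytoplasm 1039 (highest other 0), knockdown cytoplasm 2313 (0) and nuclei 1383 (1), T4 1320 (0), 408 (0) and 19 (1), and nucleus against cytoplasm 3998 (1) and 5814 (0). For site use the counts were 0 in LM2 cytoplasm (0), 0 in LM2 nuclei (143), 128 (0) and 40 (0) after the knockdown, 38 (0), 16 (0) and 0 (1) for T4, and 107 (0) and 290 (0) between fractions, so that 10 of 10 splits reached the comparisons with 0 calls. The split with 1247 calls keeps both nuclear libraries numbered 2 together and points to a structure of the samples. In that comparison, splits that part the libraries of every number gave 0 other calls. For differences of effects with 0 calls, 100 of 100 splits reached them (LM2: highest 226 in site use and 2457 in expression, knockdown: 30 in site use). Such splits can keep a real effect in a single fraction, and which libraries they put together was not kept. Their counts therefore do not by themselves show a structure of the samples.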

How the results depend on the processing

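Alternatives added after the data were seen were library totals alone, the ends of other annotation versions, leaving out both nuclear libraries numbered 2 (with all libraries or with nuclei alone) and leaving out library 3 of T4 at 6 h. Of 406 calls of named genes, 282 were kept without each library in turn, 262 under every alternative, 239 under both, and 0 changed direction. HNRNPC after the knockdown ranged over −2.57 to −2.17 across settings and fractions and stayed past the threshold. Where a result changed, the cause was not tested.

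The replicate block gave 13 calls for LM2 site use in cytoplasm (0 without it), 6 at 24 h of T4 (16), 1 for the knockdown difference in expression (2), and 7 for T4 expression at 72 h (19), where the numbers pair. It moved no other count of calls by more than 1.5 times. It ended 35 calls of named genes, 5 of them where the numbers pair: DUSP6 in LM2 nuclei (adjusted p = 0.060) and COL6A1, C11orf68, INSIG1 and SLCO4A1 at 72 h of T4 (0.057, 0.051, 0.051 and 0.051). Elsewhere libraries share only a number: 4 of 6 libraries correlated best with their own number for LM2 cytoplasm and 0 of 6 for the knockdown in either fraction. The block gave each number 1 effect shared by all groups of a table. It can remove only in part a pairing that differs between fractions or harvests. For number 2, Par nuclei and cytoplasm deviated in opposite directions in expression (correlation −0.33). No block was fitted within nuclei alone or within the 72 h groups alone. The limma test with pseudocount 1, planned for normalised values, was run as an alternative to edgeR, the test planned for counts.

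Site use, by comparison. LM2 cytoplasm (0): 8 with no site filter, 25 with site means of at least 50, 8 with extreme sites, 12 with other annotation versions, 1, 11 and 2 by limma with pseudocounts 1, 5 and 0.1, 86 by diffSplice, 189 with the compared groups alone and 123 without nuclear libraries 2. LM2 nuclei (0): 1 with no filter. Nucleus against cytoplasm, Par (107): 59 with means of at least 50, 190 by diffSplice and 216 without nuclear libraries 2, and gCTRL (290): 91 with means of at least 50. LM2 difference (0): 1 by diffSplice. Knockdown cytoplasm (128): 42 with means of at least 50, 72 with pseudocount 0.1 and 199 by diffSplice. Knockdown nuclei (40): 25 and 26 with means of at least 50 and extreme sites. Knockdown difference (0): 2 with means of at least 50. T4 6 h (38): 10, 77 and 8 with means of at least 50, diffSplice and the compared groups alone. T4 24 h (16): 6 with means of at least 50, 6 with pseudocount 0.1, 30 by diffSplice, 74 with groups alone and 70 without library 3 of T4 at 6 h. The 24 h and 6 h difference (7): 2, 3, 14 and 2 with no filter, means of at least 50, diffSplice and groups alone. The 72 h and 6 h difference (11): 6 and 35 with means of at least 50 and diffSplice.

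Expression. LM2 cytoplasm (1039): 292 with totals, 571 after quantile normalisation, 2537 with groups alone and 1741 without nuclear libraries 2. LM2 nuclei (232): 116, 143 and 40 with totals, quantile and groups alone, and 65 with nuclei alone without libraries 2. LM2 difference (0): 1 by limma with pseudocount 5 and 4 by DESeq2. Knockdown difference (2): 36 with no filter, 10 with totals, 4 with quantile and 27 by DESeq2. T4 6 h (1320): 793 with quantile and 421 with groups alone. T4 24 h (408): 765 by DESeq2, 2004 with groups alone and 1287 without library 3 of T4 at 6 h. T4 72 h (19): 32 with quantile, 83 by DESeq2, 5 with groups alone and 120 without that library. The 24 h and 6 h difference (759): 424 with quantile. The 72 h and 6 h difference (782): 1402, 458 and 486 with totals, quantile and groups alone. HNRNPC was past the threshold with cytoplasm alone in LM2 cells (−0.33) and not past it with quantile in Par nuclei (+0.75). PDLIM5 site use changed sign in LM2 nuclei without libraries 2 (−0.12, and −0.10 with nuclei alone) and in knockdown cytoplasm with no filter (+0.0101). Correlations with means of at least 50 were 0.172 (knockdown and LM2, nuclei) and −0.370 (T4 6 h and knockdown).

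Leaving out each library of the compared groups gave these ranges (library 3 of T4 at 6 h, left out of the 24 and 72 h fits, is given above). Site use: 0 to 37 (LM2 cytoplasm), 26 to 124 (Par), 67 to 163 and 18 to 42 (knockdown cytoplasm and nuclei), 179 to 287 (gCTRL), 22 to 40 and 2 to 6 (T4 6 and 24 h), 2 to 13 and 8 to 18 (differences of 24 and 72 h from 6 h). Expression: 340 to 1045 and 128 to 311 (LM2 cytoplasm and nuclei), 0 to 5 (LM2 difference), 878 to 1150 (knockdown nuclei), 1 to 14 (knockdown difference), 143 to 220 and 6 to 12 (T4 24 and 72 h), 536 to 1252 and 484 to 841 (differences from 6 h). HNRNPC: −0.43 to +0.0213 (LM2 nuclei), and −0.32 to +0.10, −0.16 to +0.0063 and −0.12 to +0.18 (T4 6, 24 and 72 h). PDLIM5: −1.21 to +1.42 in site use and −1.23 to +2.46 in expression (LM2 nuclei), −0.39 to +0.41 and −0.0725 to +0.57 (knockdown cytoplasm and nuclei), and −0.00826 to +1.39 (T4 72 h). Correlations: −0.039 to 0.113 (knockdown and LM2, nuclei), −0.493 to −0.215 (cytoplasm) and 0.113 to 0.501 (T4 6 h and LM2 cytoplasm).

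Scalings moved the median log2 of all genes by more than 0.1 as follows: LM2 cytoplasm +0.12 with median-of-ratios and with DESeq2, LM2 difference −0.13 with each, Par fractions −0.26 with quantile, knockdown cytoplasm +0.14 and nuclei −0.12 with totals, knockdown difference −0.25 with totals, gCTRL fractions +0.11 with totals and −0.30 with quantile, T4 6 h −0.40 and +0.18, 24 h −0.20 and 72 h +0.16 with totals, 24 h and 6 h difference −0.13 with median-of-ratios and with DESeq2, +0.20 with totals and −0.21 with quantile, and 72 h and 6 h difference +0.57 with totals and −0.17 with quantile. Splits of the differences from 6 h were 608 higher and 151 lower at 24 h (484 and 218 with median-of-ratios, 561 and 394 with DESeq2, 254 and 170 with quantile, 670 and 48 with totals) and 660 and 122 at 72 h (333 and 125 with quantile, 688 and 286 with DESeq2, 1371 and 31 with totals). At the depth of these libraries, site use could be tested only in the 636 to 899 genes with enough reads at both sites and a known order of the sites.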

Other observations

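All observations here were chosen after the results were seen. AHNAK differed between fractions and after T4: its distal share was 98.1 ± 0.638% against 56.0 ± 9.80% in gCTRL nuclei and cytoplasm, and in LM2 cells 15.7 ± 10.9% against 95.8 ± 3.12% with T4 at 6 h and DMSO, while its expression, summed over all entries, rose at 6 h (log2 +2.19 ± 0.23). With the shift toward the proximal site, this does not show a rise of the mRNA that ends at the distal site. EIF4A2 moved toward its proximal site in knockdown cytoplasm (at least 4.77-fold), in gCTRL nuclei against cytoplasm (at least 9.5-fold) and after T4 at 6 h (log2 −4.85 ± 0.69). Knockdown cytoplasm and gCTRL nuclei were set against the same gCTRL cytoplasm libraries without proximal reads, and had 20 and 18 such reads. As given above, the knockdown call was lost with no site filter, and the T4 call with the 6 h groups alone. SLCO4A1-AS1 was higher in LM2 than Par cytoplasm (log2 +2.51 ± 0.29) and lower after the knockdown (log2 −2.86 ± 0.25).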
